A study of Mus musculus with 42 samples.

How the data were processed

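Total RNA of mouse cortex, and RNA of cortical nuclei purified through iodixanol, was sequenced single-end from directional libraries, in males of 7 to 8 weeks (KO cohort), males of 7 to 10 weeks (OE cohort) and both sexes (Dnmt3a cohort). Per the labels the authors used Trim Galore, Bowtie, STAR and bedtools on mm9, without versions, and the role of each tool is not stated.

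The counts in the deposited table are whole numbers per gene that the authors made from aligned reads, without scaling. Whether a count column is exonic or intronic was settled by comparing fold changes from it with the authors' fold changes of each kind. Spearman's rho was 0.929 for the nuclear columns against the authors' nuclear intronic values and 0.590 against their exonic ones, so these columns were taken as intronic counts. The 2 columns per nuclear library were summed. The log2 values are fold changes of mutant over WT that the authors deposited, and those of the Dnmt3a cohort were read as log2 by analogy with the other columns of the same table. The adjusted p-values and FDR values beside them are the authors' as deposited. The fraction of methylated calls at CA sites of each gene body is as deposited by the authors, in a column whose name gives no age or origin. The name of the CA coverage column points to earlier data from animals of 8 weeks. Whether both columns come from the same data is not stated. Gene positions, CA coverage and membership of 2 gene lists are further deposited values, in base pairs, calls and true or false. Another 172 columns of values per sample were not used, 162 of them from ChIP-seq and 10 intronic columns whose samples could not be told.

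The table holds 23268 genes, of which 3926 overlap a gene on the other strand and 966 lie on the sex chromosomes or unplaced sequence and were left in. Each cohort and fraction was fitted alone with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F test), and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to pass or to be called. SE is the log2 fold change divided by the square root of F. The difference of the KO effect between fractions was an interaction term over intronic counts of 24 libraries. Replicate numbers were taken to pair libraries where every correlation of same-numbered deviations was above 0.1, which held in KO whole cells (0.305 to 0.951) and KO nuclei (0.174 to 0.664) and not in OE (-0.316 to 0.335), whole-cell introns (-0.166 to 0.211) or between fractions (0.0900 to 0.243). The rule is a weak one in KO whole cells, where 4 of 6 numbers correlated best with their own. The value of 0.951 there is that of replicate 1. In both genotypes its whole-cell exonic library carries excess counts at genes that overlap an opposite-strand gene. Whether that excess also shaped the correlations of the other replicates was not tested. Replicates 4 and 6 did better with another number there (0.355 against 0.305 and 0.463 against 0.421), as did nuclear replicate 6 (0.241 against 0.174). Pairing by number is therefore uncertain, above all in whole cells. The fits with replicate as a block stand beside the planned fits without it.

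The 28 gene lists tested in the 3 main comparisons were written from general knowledge, and a list of nuclear-retained long noncoding RNAs was kept for the comparison of fractions. They cover activity-regulated, presynaptic, glutamate and GABA receptor, potassium channel, axon guidance, cadherin, contactin, interneuron, upper-layer, deep-layer, astrocyte, myelin, oligodendrocyte precursor, microglia, endothelial, choroid plexus, striatal, red blood cell, cholesterol, oxidative phosphorylation, ribosomal, glucocorticoid, methylation partner, imprinted, germline, interferon and earlier MeCP2 literature genes. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated one, adjusted over 83 tests (27 for whole-cell introns). With the preset value 23 tests passed, and 0 did with the estimated one by the same tool.

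The genes named are Mecp2, Irak1, Dnmt3a and Actl6b, then the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and every mutant library on the same side of the WT mean (5 and 5 between fractions). Predicted and clone names, pseudogenes, Xist and Y genes were left out. For each list up to 4 called members of smallest adjusted p, or else 2 of smallest p, could be named, and for each overlap the 8 genes of smallest larger adjusted p. Pdgfra, Olig2 and Tsc22d3 in KO whole cells, Egr1, Arc and Fos in KO nuclei and Mbp in OE fall outside this rule and were chosen after their values were seen. The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

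For long genes (over 100 kb) and for the top 10% by mCA, the median of log2 CPM centred per gene was taken per library minus that of other genes, and groups were compared by exact two-sided permutation of libraries, adjusted over 8 tests. Overlaps of calls were set against the product of the 2 set sizes over the genes tested in both, with Fisher's exact test. Alternatives were DESeq2 1.42.0, limma voom, other scalings and filters, thresholds of 0.1 and 0.01, each library left out in turn, and the replicate block. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

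The fits were tested on simulated data with 100 genes changed at each size. Of 1.5-fold changes 58 were recovered in KO whole cells, 67 in nuclei, 74 in OE, 42 in whole-cell introns and 22 for the interaction, and of 2-fold changes 92, 89, 91, 93 and 64. Median fold changes of all genes stayed between -0.01 and 0.03 under each scaling.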

Results

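RNA sequencing of mouse cerebral cortex was available as 42 samples in 8 groups, collected to follow how MeCP2, a protein that binds methylated DNA in neurons, and DNMT3A, the enzyme that writes non-CG methylation there, shape expression. Total RNA came from 6 Mecp2 knockout (KO) and 6 wild-type (WT) male cortices, nuclear RNA from 6 KO and 6 WT samples of the same cohort, and total RNA from 5 males that overexpress Mecp2 (OE) and 5 WT males of their own cohort. Per the labels the OE cohort is of the FVB strain and the others of C57BL/6J, so each mutant group was compared only with WT of its own cohort. Another 4 animals with Dnmt3a removed from neurons by Baf53b-Cre (cKO) and 4 WT, with 2 of each sex per genotype, completed the series. Counts per library were used for 34 samples, and the Dnmt3a animals entered only through the authors' deposited table of fold changes, since counts per library of that cohort were not analysed here. Exonic counts summed to 3963732 to 25755693 per whole-cell library in the KO cohort and to 16058617 to 24006538 in the OE cohort. Intronic counts summed to 7091819 to 14023482 per nuclear library and to 812488 to 5051252 per whole-cell library of the KO cohort. The nuclear columns hold intronic counts, so every nuclear value describes intronic, largely unspliced RNA. All positions are mm9. The p-values of edgeR and of permutations over libraries measure the spread between these animals' samples. Those of Fisher's exact tests are over genes, and camera at the preset correlation treats genes as nearly independent.

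Mecp2 itself moved in the direction of each genotype in exonic RNA. The gene (chromosome X, 71271930 to 71331029, minus strand) stood at 259 ± 18.6 CPM (counts per 1e6 counts; SD, n = 6) in WT and 6.72 ± 0.624 CPM in KO cortex, a log2 fold change of -5.27 (SE 0.08, adjusted p = 3.78e-14). In OE cortex Mecp2 rose from 253 ± 18.0 to 569 ± 16.9 CPM (SD, n = 5), a log2 fold change of 1.17 (SE 0.06, adjusted p = 3.42e-08). Intronic Mecp2 counts ran the other way in KO, from 69.2 ± 9.97 to 216 ± 67.9 CPM in nuclei and from 72.1 ± 19.9 to 205 ± 15.1 CPM in whole cells (SD, n = 6). Irak1, an interleukin-1 receptor kinase gene on the same strand (chromosome X, 71259252 to 71269257), rose in KO from 35.6 ± 2.56 to 65.6 ± 5.95 CPM in exonic counts and from 24.7 ± 1.75 to 49.96 ± 4.77 CPM in nuclear counts. In OE cortex Irak1 read -0.07 (adjusted p = 0.587).

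**Figure D1:**
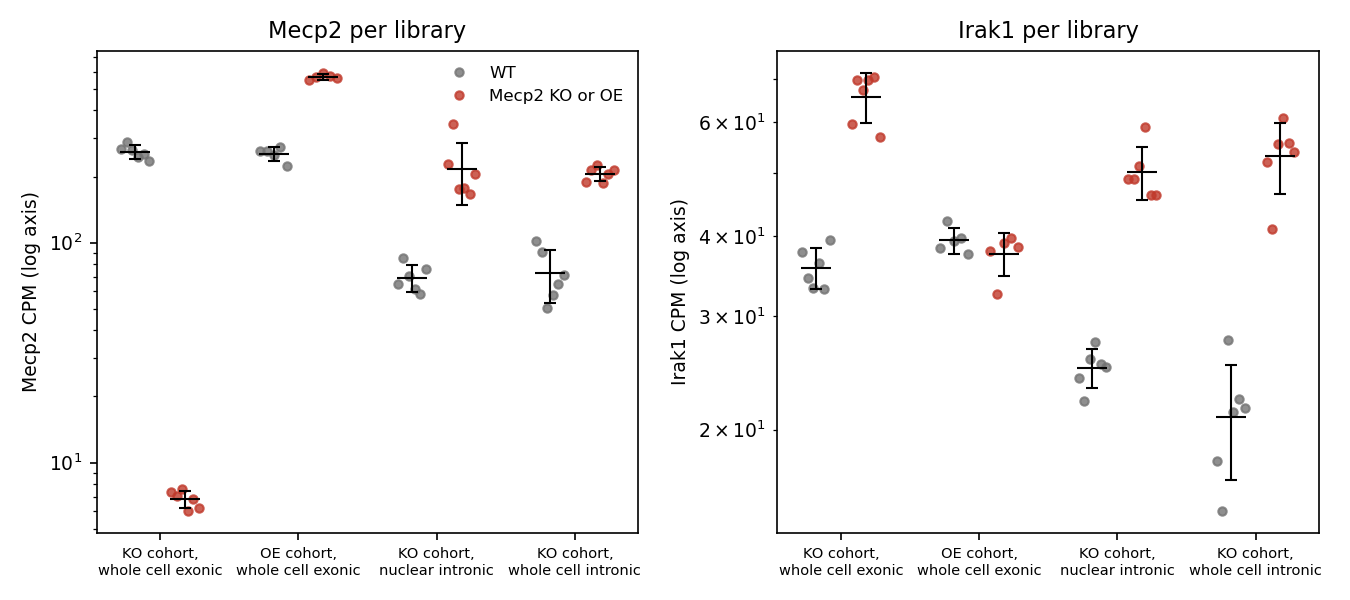
CPM (log axis) of Mecp2 and Irak1 in each library, as points, with the mean and SD of each group, for whole-cell exonic, nuclear intronic and whole-cell intronic counts. KO exonic Mecp2 lies near 6.72 CPM against 259 CPM in WT, while nuclear intronic Mecp2 and Irak1 lie above WT in 6 of 6 KO libraries.

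A small set of genes passed the edgeR test in KO whole cortex, among them the adhesion gene Sdk1 and the calcium channel gene Cacna1g. Among the genes that rose were Sdk1, a synaptic adhesion molecule of the immunoglobulin family, by a log2 fold change of 0.77 (SE 0.09, adjusted p = 0.00211), and Agxt2l1, an astrocyte-rich phospholyase, by 1.46 (SE 0.22, adjusted p = 0.0173). Sdk1 (chromosome 5, 141717443 to 142691540) went from 20.2 ± 2.04 to 34.6 ± 3.73 CPM and Agxt2l1 (chromosome 3, 130320365 to 130338668) from 12.6 ± 3.69 to 34.4 ± 10.98 CPM (SD, n = 6). Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, rose by 0.97 (SE 0.19, adjusted p = 0.0437). Cacna1g, a T-type calcium channel gene (chromosome 11, 94269704 to 94335414), fell by 0.80 (SE 0.09, adjusted p = 0.00211), from 130 ± 19.9 to 74.9 ± 5.05 CPM. Abca8a, an ABC transporter gene (chromosome 11, 109886947 to 109957292), fell by 1.27 (SE 0.16, adjusted p = 0.00370), from 6.61 ± 1.14 to 2.71 ± 0.507 CPM.

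In all, 69 of 13749 tested genes passed the test in whole cells (31 higher, 38 lower in KO), and 262 did (117 higher, 145 lower) when replicates of the same number were paired as blocks, with all 69 among them. The other large rises were those of the serine protease gene Htra4 (1.08), the cold-inducible RNA-binding protein gene Cirbp (0.83), the transcription elongation scaffold gene Aff1 (0.67) and Bmper, a secreted regulator of BMP signalling (0.67). Pappa2, a protease that cuts insulin-like growth factor binding proteins, fell by 2.65 (SE 0.46, adjusted p = 0.0296). The cell polarity gene Crb1 fell by 1.46, Tbata by 1.32, the glycine receptor gene Glra3 by 1.28, the monoamine transporter gene Slc29a4 by 1.26 and the lactase gene Lct by 1.26. With intronic in place of exonic counts Cirbp read -0.03. Dnmt3a read -0.24 (SE 0.07, adjusted p = 0.164) and Actl6b, the gene whose promoter drives the Cre of the other cohort, 0.06 (adjusted p = 0.776).

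Oligodendrocyte precursor markers stood lower in KO whole cells, with 0 of 12 members positive, a median of -0.42 and Gpr17, a receptor of committed precursors, past the test at -0.57 (adjusted p = 0.0293). The growth factor receptor gene Pdgfra read -0.32 and the lineage factor gene Olig2 -0.49, and 10 of the 12 passed when adjusted over the list alone (8 over all genes with the block). The camera test gave the list adjusted p = 9.29e-11, and adjusted p = 0.251 with an estimated correlation. Glucocorticoid-responsive genes stood higher, with 19 of 20 members positive and a median of 0.34 (adjusted p = 5.40e-07, and adjusted p = 0.599 with an estimated correlation). Only Fkbp5 of that list passed over all genes and 4 passed when adjusted over the list alone, among them Tsc22d3, a steroid-induced leucine zipper gene, at 0.48. Myelin genes of mature oligodendrocytes did not pass without the block (0 of 16 positive, median -0.21, adjusted p = 0.0965, and adjusted p = 0.866 with an estimated correlation), with Gjc2, an oligodendrocyte gap junction gene, at -0.51. With the block they did (2 of 16 positive, adjusted p = 0.00807, and adjusted p = 0.770 with an estimated correlation).

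Genes of translation and respiration stood slightly higher in KO whole cells. Cytosolic ribosomal protein genes had 24 of 24 members positive at a median of 0.15 (adjusted p = 4.23e-04, and adjusted p = 0.845 with an estimated correlation), with Rps4x at 0.27 and 0 called over all genes or adjusted over the list alone. Oxidative phosphorylation genes had 24 of 26 positive at a median of 0.10 (adjusted p = 5.49e-04, and adjusted p = 0.599 with an estimated correlation), with 0 called in the same ways and Atp5a1 at 0.16. Receptor genes stood lower, GABA receptors with 2 of 15 positive (adjusted p = 0.0131) and glutamate receptors and scaffolds with 7 of 26 (adjusted p = 0.0240), each with adjusted p = 0.599 with an estimated correlation. Of these receptors 0 passed over all genes by edgeR, while Gabra2 at -0.52 and Gabra3 at -0.16 passed when adjusted over the list alone and Grin3a read -0.43. Microglia markers had 2 of 16 positive (adjusted p = 0.0143, and adjusted p = 0.866 with an estimated correlation), and Fcrls, an Fc receptor-like gene of microglia, fell by 0.72 (adjusted p = 0.0487), alone over all genes and over the list alone.

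The remaining 20 lists did not pass in KO whole cells without the block (adjusted p = 0.0919 to 0.904, and 0.713 to 0.961 with an estimated correlation). With it axon guidance genes did (adjusted p = 0.0466, and adjusted p = 0.693 with an estimated correlation). Within them the interneuron calcium-binding protein gene Calb2 fell by 0.86 (adjusted p = 0.0286) and Cntnap5b, a contactin-associated adhesion gene, by 0.42 (adjusted p = 0.0406). Auts2, a gene of neuronal development, rose by 0.47 (adjusted p = 0.0444) and the imprinted gene Nap1l5 by 0.42 (adjusted p = 0.0379). Adjusted over the list alone, contactins and other adhesion genes had 6 called, imprinted genes 4, earlier MeCP2 literature genes 4, and axon guidance, cadherin, interneuron and methylation partner lists 3 each. Choroid plexus and meninges markers had 4 of 13 positive, with Ttr at -5.73 (SE 1.60, adjusted p = 0.143), and striatal markers had 9 of 13 positive.

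The size of the whole-cell set depended on single libraries and on the tool. By edgeR 1719 of 13749 genes had an unadjusted p under 0.05. In the authors' deposited values for the same exonic comparison 370 of 13836 genes passed an adjusted p of 0.05. DESeq2 called 345 genes, no filter on low counts left 36, leaving out the genes that overlap an opposite-strand gene gave 110, and leaving out both replicate 1 libraries, which carry excess counts at genes that overlap an opposite-strand neighbour, gave 29. The count was 44, 33, 20 or 14 without WT replicate 1, 4, 5 or 6, and 28, 113, 10, 15, 28 or 22 without KO replicate 1, 2, 3, 4, 5 or 6.

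In KO nuclei, where introns were counted, Npas4, a transcription factor gene that neuronal firing switches on, fell. Npas4 (chromosome 19, 4984354 to 4989971) went from 29.9 ± 11.5 to 8.47 ± 4.02 CPM (SD, n = 6), a log2 fold change of -1.82 (SE 0.29, adjusted p = 0.0108). Robo3, an axon guidance receptor gene, fell by 1.03 (adjusted p = 4.39e-05) and Cacna1g by 0.93 (SE 0.09, adjusted p = 7.73e-05). Ptgfrn, an immunoglobulin-type membrane protein gene (chromosome 3, 100844154 to 100914201), rose from 37.2 ± 6.00 to 66.9 ± 4.53 CPM, by 0.85 (SE 0.09, adjusted p = 2.31e-04). Intronic Mecp2 rose by 1.64 (SE 0.16, adjusted p = 7.59e-05) and Irak1 by 1.02 (SE 0.08, adjusted p = 9.67e-06).

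Of 14054 genes tested in nuclei 62 passed (24 higher, 38 lower in KO), and 1059 did (516 higher, 543 lower) with the replicate block, with all 62 among them. The GABA receptor gene Gabrr2 rose by 1.42, Agxt2l1 by 1.38, the ketone synthesis gene Hmgcs2 by 1.38, Bmper by 0.82 and Tead1, a transcription factor gene of the Hippo pathway, by 0.66. Colq, which anchors acetylcholinesterase and overlaps Hacl1 on the same strand, fell by 1.70, the olfactory receptor gene Olfr78 by 1.26, Cd300lg by 1.24 and Slc29a4 by 1.18. Stc1, a secreted glycoprotein gene, fell by 1.14 and the lectin gene Clec18a by 1.08 (SE 0.13, adjusted p = 5.68e-04). Mndal fell by 1.12, in a span that it shares with Ifi203 and Mnda, so that its counts cannot be given to 1 gene. Dnmt3a read -0.06 (adjusted p = 0.880) and Actl6b -0.08 (adjusted p = 0.818).

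The activity-regulated list had 1 of 19 members positive in KO nuclei and a median of -0.80, with 9 members past the test when adjusted over the list alone and 10 over all genes with the block. Egr1 read -1.47, Arc -1.26 and Fos -1.37, all early response genes. The camera test gave the list adjusted p = 1.73e-06, and adjusted p = 0.599 with an estimated correlation. The same list in KO whole-cell exonic counts had 16 of 21 members positive, a median of 0.14 and adjusted p = 0.550. That contrast sets introns against exons as well as nuclei against whole cells. In whole-cell intronic counts the list also stood lower, as given below. The difference between fractions was tested on intronic counts of both, where 0 of 14272 genes passed.

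Oligodendrocyte precursor markers also stood lower in KO nuclei, with 1 of 11 positive (adjusted p = 2.79e-04, and adjusted p = 0.182 with an estimated correlation), the complement-like gene C1ql1 at -0.81, and 3 called when adjusted over the list alone against 0 over all genes. Glucocorticoid-responsive genes stood higher with 17 of 20 positive (adjusted p = 1.20e-04, and adjusted p = 0.599 with an estimated correlation), with Fkbp5 at 1.09 (adjusted p = 0.233) and 0 called over all genes or over the list alone. Striatal neuron markers, genes of a neighbouring tissue, had 11 of 12 positive (adjusted p = 0.00490, and adjusted p = 0.713 with an estimated correlation), with the dopamine receptor gene Drd2 at 0.76. Imprinted genes had 13 of 16 positive (adjusted p = 0.0101, and adjusted p = 0.599 with an estimated correlation), with the growth regulator gene Plagl1 at 0.45 (adjusted p = 0.0514) and 3 called when adjusted over the list alone. Axon guidance genes had 24 of 30 positive (adjusted p = 0.0239, and adjusted p = 0.866 with an estimated correlation), with the guidance cue gene Sema5a at 0.49. The remaining 21 lists did not pass without the block (adjusted p = 0.0760 to 0.926, and 0.599 to 0.961 with an estimated correlation), among them myelin markers with 7 of 16 positive, and Calb2 read -0.80 (adjusted p = 0.175). With the block glutamate receptors (adjusted p = 0.00612), GABA receptors (adjusted p = 0.0291), endothelial markers (adjusted p = 0.0329) and presynaptic genes (adjusted p = 0.0431) passed, at adjusted p = 0.638 to 0.724 with an estimated correlation.

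In the authors' deposited values for nuclear introns 195 of 14076 genes passed an adjusted p of 0.05 (100 higher, 95 lower in KO). That count lies between the 62 without the block and the 1059 with it. DESeq2 called 177 genes in nuclei, with 54.2% of them higher against 38.7% by edgeR, and leaving out both replicate 1 libraries gave 18, or 786 with the block. The count was 29, 21, 30 or 25 without WT replicate 1, 3, 4 or 5, and 33, 29, 33 or 28 without KO replicate 1, 3, 4 or 6, and the 555 genes with the block and both replicate 2 libraries out again held all 62.

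**Figure D2:**
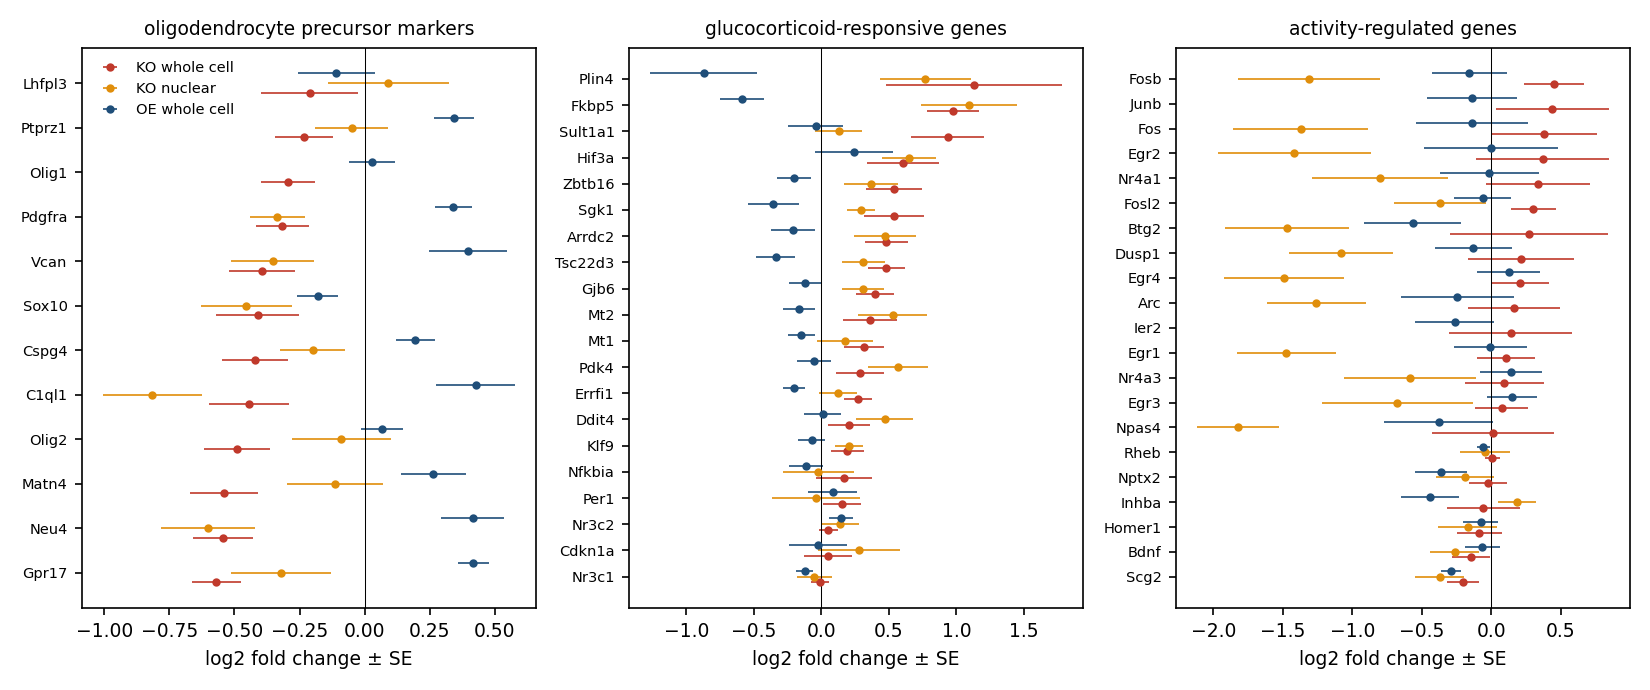
Log2 fold change with its SE for each member of the oligodendrocyte precursor, glucocorticoid-responsive and activity-regulated lists in KO whole cells, KO nuclei and OE whole cells. Of the precursor markers 0 of 12 were positive in KO whole cells, 1 of 11 in KO nuclei and 10 of 12 in OE.

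In OE whole cells 978 of 14644 genes passed the test (468 higher, 510 lower in OE, n = 5 per group), more than in KO whole cells, where the biological coefficient of variation was 0.214 against 0.0984 in OE. Crlf1 and Clcf1, whose products form a secreted ligand of the CNTF receptor, rose together, Crlf1 (chromosome 8, 73017056 to 73027980) by 2.12 (SE 0.17, adjusted p = 1.69e-05) from 2.85 ± 0.867 to 12.4 ± 1.55 CPM and Clcf1 by 1.64 (SE 0.38, adjusted p = 0.0184). The adhesion gene Sdk1 fell by 1.27 (SE 0.10, adjusted p = 1.21e-05), from 22.9 ± 1.63 to 9.52 ± 1.37 CPM, and Bmper by 1.16 (SE 0.13, adjusted p = 2.50e-04), both opposite to KO. Fhdc1, a formin gene of the cytoskeleton (chromosome 3, 84247946 to 84284351), fell by 1.41 (SE 0.12, adjusted p = 2.89e-05). Cacna1g rose by 0.90 (adjusted p = 3.80e-06).

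Among the other large rises in OE were the retinoic acid synthesis gene Aldh1a3 (1.88), the RGS anchor gene Rgs9bp (1.85), the matrix gene Postn (1.70), Olfr78 (1.69), the neuropeptide receptor gene Npbwr1 (1.66) and the BMP co-receptor gene Hfe2 (1.65). The chloride channel gene Clcnka fell by 3.70 (SE 0.46), from 2.43 ± 1.37 to 0.193 ± 0.116 CPM, the LIM-domain gene Pdlim1 by 1.38 and the matrix gene Papln by 1.29. Ntn5, a netrin gene that overlaps Sec1 on the other strand, fell by 1.19. Ttr, which choroid plexus expresses strongly, fell by 2.74 (SE 0.68, adjusted p = 0.0272), with WT libraries at 12.5 ± 12.2 CPM. Dnmt3a read 0.13 (adjusted p = 0.261) and Actl6b -0.03 (adjusted p = 0.857).

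The oligodendrocyte precursor and myelin lists leaned opposite ways in OE cortex, and the difference between these lists was not tested. Precursor markers stood higher, with 10 of 12 positive and Gpr17 (0.42), Pdgfra (0.34) and Ptprz1 (0.34) past the test over all genes and 7 adjusted over the list alone (adjusted p = 0.00107, and adjusted p = 0.599 with an estimated correlation). Myelin markers stood lower with 0 of 16 positive and a median of -0.42, with the iron carrier gene Trf past the test at -0.53 and 13 past it when adjusted over the list alone, among them Mbp at -0.54 (adjusted p = 1.73e-07, and adjusted p = 0.604 with an estimated correlation). Deep-layer neuron markers stood lower with 3 of 17 positive, Tbr1 (-0.38), Sulf1 (-0.56) and Tle4 (-0.40) past the test and 10 adjusted over the list alone (adjusted p = 2.79e-04, and adjusted p = 0.599 with an estimated correlation). Striatal markers had 0 of 14 positive and a median of -0.54, with Scn4b, a sodium channel subunit gene, at -0.72 the 1 call over all genes and over the list alone (adjusted p = 0.00708, and adjusted p = 0.865 with an estimated correlation).

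Axon guidance genes had 7 of 30 positive in OE, with 9 called over all genes (2 higher) and 13 adjusted over the list alone (adjusted p = 1.58e-04, and adjusted p = 0.491 with an estimated correlation). The semaphorin genes Sema5a and Sema3e fell by 0.68 and 0.81 and the ephrin gene Efna5 by 0.55, whereas the receptor gene Plxnd1 rose by 0.52. Imprinted genes had 8 of 22 positive, with 7 called (1 higher) and 8 adjusted over the list alone (adjusted p = 0.00109, and adjusted p = 0.491 with an estimated correlation), Plagl1 at -0.67, Nap1l5 at -0.47 and Grb10, a growth inhibitor gene, at 0.30. Oxidative phosphorylation genes had 3 of 26 positive, with Atp5b, Atp5a1, Uqcrc1 and Ndufv1 past the test at -0.18, -0.18, -0.21 and -0.24 and 5 adjusted over the list alone (adjusted p = 3.09e-06, and adjusted p = 0.599 with an estimated correlation).

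Receptor genes stood higher in OE, glutamate receptors and scaffolds with 20 of 26 positive, 6 called (5 higher) and 11 adjusted over the list alone (adjusted p = 8.06e-04, and adjusted p = 0.599 with an estimated correlation). Shank2, a postsynaptic scaffold gene, rose by 0.21 and the glutamate receptor gene Grm8 fell by 0.37. GABA receptors had 11 of 15 positive, with Gabra3 (0.31) and Gabra5 (0.26) past the test and 3 adjusted over the list alone (adjusted p = 0.0240, and adjusted p = 0.713 with an estimated correlation). Glucocorticoid-responsive genes had 4 of 20 positive, with Fkbp5 falling by 0.59 (adjusted p = 0.0442) and 0 called over the list alone (adjusted p = 0.0407, and adjusted p = 0.845 with an estimated correlation).

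The other 18 lists did not pass in OE (adjusted p = 0.0501 to 0.904, and 0.713 to 0.961 with an estimated correlation), though several members did. Contactins and other adhesion genes had 9 called (1 higher) and 11 adjusted over the list alone, with Cntnap4 falling by 0.67, Ncam2 by 0.40, Cntn4 by 0.36 and Auts2 by 0.33. Cadherins had 4 called and 6 adjusted over the list alone, with Cdh18 falling by 0.69 and Cdh6 by 0.76. The interneuron genes Pvalb, Npy and Cck fell by 0.64, 0.43 and 0.37, and 6 passed when adjusted over the list alone. Potassium channels had 5 called both over all genes and over the list alone, among them Kcnip1 (0.33) and Kcna1 (-0.34). The microglia genes Fcrls (0.72) and C1qc (0.49), the stress hormone gene Crh (0.62), the presynaptic gene Nrxn2 (0.31), the astrocyte gene Aldoc (0.29) and the interferon-induced gene Ifit2 (0.49) rose, and the activity-linked gene Scg2 (-0.29) fell. Choroid plexus and meninges markers had 9 of 13 positive, a median of 0.32 and a mean of -0.06.

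Numbers did not pair the OE libraries, and a fit with them as blocks gave 997 genes, 821 of them shared, against 1059 in KO nuclei with the block. The count was 617 or 637 without WT replicate 3 or 4, and 579 without OE replicate 5.

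The comparison of KO with OE asked which genes respond to MeCP2 in both directions, in cohorts that also differ in strain. Of the genes tested in both, 43 were called in both in opposite directions and 0 in the same direction by edgeR, where 2.35 and 2.38 would be shared by independent sets. They comprised 16 genes higher in KO and lower in OE (1.15 expected, Fisher's exact p = 1.76e-15) and 27 lower in KO and higher in OE (1.20 expected, Fisher's exact p = 1.19e-32). Besides Mecp2, Cacna1g, Sdk1 and Abca8a (0.80 in OE), the genes of smallest adjusted p were the cyclin gene Ccnd1 (-0.72 in KO, 0.56 in OE), the zinc finger gene Tshz1 (0.67, -0.71), the growth factor homologue gene Fgf11 (-1.18, 0.89) and the lipoprotein lipase gene Lpl (-1.004, 1.05). Across 13650 genes, which are not independent replicates, the fold changes had Pearson's r = -0.469 and Spearman's rho = -0.490.

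Nuclear KO calls gave 30 genes opposite to OE and 1 in the same direction, Mecp2, whose intronic counts are the nuclear measure. Ptgfrn (0.85 in KO nuclei, -0.79 in OE), Robo3 (-1.03, 0.78), Clec18a (-1.08, 0.87), Olfr78 (-1.26, 1.69) and the actin-linked gene Afap1l1 (0.57, -0.60) were among them. With the replicate block in the KO fit, 142 whole-cell and 276 nuclear calls ran opposite to OE, where 8.91 and 34.2 were expected. In the same direction ran 0 and 2. For same-direction calls in whole cells, DESeq2 also gave 0, and at the looser adjusted p of 0.1 edgeR gave 0. Without both replicate 1 libraries of the KO cohort the 43 became 16, and it was 25, 22, 13 or 9 without WT replicate 1, 4, 5 or 6 and 16, 7, 9, 18 or 15 without KO replicate 1, 3, 4, 5 or 6.

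**Figure D3:**
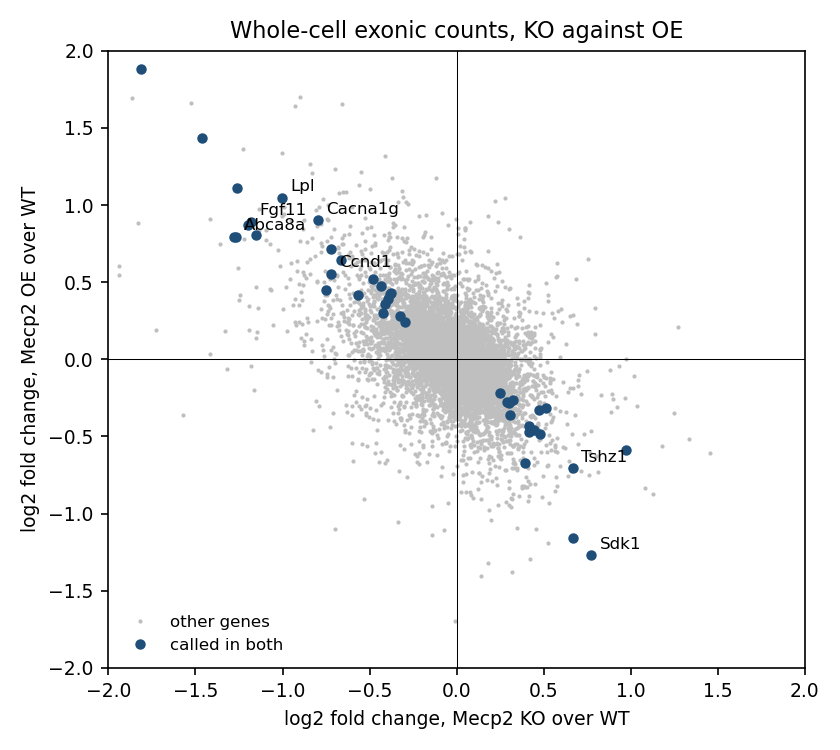
Log2 fold change in KO (x) against OE (y) whole cells, 1 point per gene tested in both, with genes called in both marked; 8 genes lie outside the limits of 2 log2 units. The 43 genes called in both sit in the quadrants of opposite sign.

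The KO effect in nuclei was set against that in whole cells on intronic counts of both. By edgeR 0 of 14272 genes passed for a difference of the KO effect between fractions, 355 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. Calls of the separate fits shared 11 genes in the same direction (117 with the block), and Mecp2 alone ran opposite, since its exonic counts fell and its intronic counts rose. Across 12764 genes, which are not independent replicates, the whole-cell exonic and nuclear fold changes had Pearson's r = 0.461.

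Whole-cell intronic counts of the KO cohort gave 11 of 12328 genes (6 higher, 5 lower). Mecp2 rose by 1.51 (SE 0.14), Irak1 by 1.37 (SE 0.14), Agxt2l1 by 1.45 (SE 0.20) and Cerkl, a ceramide kinase-like gene that overlaps Itga4 and Neurod1, by 0.81 (SE 0.15). Fgf11 fell by 1.34, the semaphorin receptor gene Plxna3 by 1.16, the Polycomb-linked genes Sfmbt2 and L3mbtl1 by 1.06 and 0.73, and Cacna1g by 1.03. Dnmt3a read -0.24 and Actl6b 0.01. Glucocorticoid-responsive genes (14 of 16 positive), oxidative phosphorylation genes (21 of 27) and ribosomal protein genes (19 of 26) stood higher, and activity-regulated genes (1 of 16), myelin markers (2 of 16) and precursor markers (0 of 7) lower, at adjusted p = 0.00220 to 0.0223, and adjusted p = 0.418 to 0.737 with an estimated correlation. DESeq2 called 31 genes, and the count was 27 without WT replicate 1 and 7 without any of WT replicate 4 or 5 or KO replicate 1, 4 or 6.

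In WT animals, nuclear and whole-cell intronic counts differed at 3217 of 13787 genes (1253 higher, 1964 lower in nuclei). The higher genes numbered 763 of 2371 without WT whole-cell replicate 6, 644 of 2340 without both replicate 1 libraries and 1880 of 4105 with the block. The mitotic cyclin gene Ccnb1 was higher in nuclei by 2.64 (SE 0.51), the tRNA methyltransferase gene Rg9mtd1 by 2.39, Ces1e by 2.20, Timd2 by 1.94 and the corepressor gene Sap30 by 1.57. The protease gene Mep1b differed by -4.68 (SE 0.30), Rab44 by -3.85, the transporter genes Slc22a27 and Slc3a1 by -3.27 and -3.19 and Slfn9 by -3.08, and Slc3a1 overlaps Prepl on the other strand. Of the list of nuclear-retained long noncoding RNAs, 4 members were in the table and 2 were tested, Snhg11 at 0.42 (adjusted p = 0.0370) and Meg3 at 0.10 (adjusted p = 0.602). How introns were counted in each column set was not stated, so that a difference in counting and the fraction itself cannot be told apart here.

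Long genes and genes rich in gene-body CA methylation (mCA), a mark that MeCP2 binds, were compared with other genes library by library. The top 10% of genes by mCA stood higher against the rest in KO nuclei by 0.11 log2 units (0.06 ± 0.09 in KO and -0.05 ± 0.05 in WT, SD, n = 6 each, exact permutation p = 0.0368). That value was higher in 6 of 6 numbered pairs (exact sign-flip p = 0.0313) and failed correction over the 8 such tests (adjusted p = 0.294, or 0.250 for sign flips). In KO whole cells the mCA difference was 0.03 (exact p = 0.517), in OE -0.05 (exact p = 0.230) and in whole-cell introns 0.07 (exact p = 0.407). Genes over 100 kb differed by 0.02 in KO whole cells (exact p = 0.273), 0.09 in KO nuclei (exact p = 0.528), -0.04 in OE (exact p = 0.151) and 0.04 in whole-cell introns (exact p = 0.734). With means in place of medians the long gene difference had an unadjusted exact p under the threshold in KO whole cells (0.0291, exact p = 0.0411, higher in 6 of 6 pairs, exact sign-flip p = 0.0313) and in OE (-0.0674, exact p = 0.0397). Without WT replicate 5 that of OE was -0.0556 (exact p = 0.0317). Between fractions the KO effects on intronic counts did not differ detectably, for long genes (permutation p = 0.791) or mCA (permutation p = 0.686). Without KO replicate 2 the nuclear long gene difference was -0.01.

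The genes that passed the test were then counted by mCA and by length, counts chosen after the calls were seen. In KO nuclei with the block, 190 of 513 higher genes with an mCA value lay in the top 10% (37.0%) against 32 of 522 lower genes (6.13%) and 9.05% of genes not called (Fisher's exact p = 3.97e-36 for higher against lower). These shares were not computed without KO replicate 2. Without the block the counts were 15 of 24 and 2 of 37 (Fisher's exact p = 1.67e-06). In KO whole cells 11 of 30 higher and 3 of 37 lower genes lay there (Fisher's exact p = 0.00613), or 45 of 105 and 20 of 139 with the block (Fisher's exact p = 9.32e-07). In OE the balance turned, with 125 of 490 lower genes (25.5%) and 45 of 438 higher genes (10.3%) in the top 10% (Fisher's exact p = 1.72e-09). Length parted the same genes. In KO nuclei with the block 52.3% of higher and 9.21% of lower genes were over 100 kb, against 15.4% of genes not called. In KO whole cells with the block the shares were 46.2% and 17.9%, and in OE 18.2% and 39.4%. Genes in the top 10% by mCA were also longer (30.1% over 100 kb against 15.9% of the rest in nuclei). These counts cannot tell mCA and length apart. Genes are not independent replicates in these counts.

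**Figure D4:**
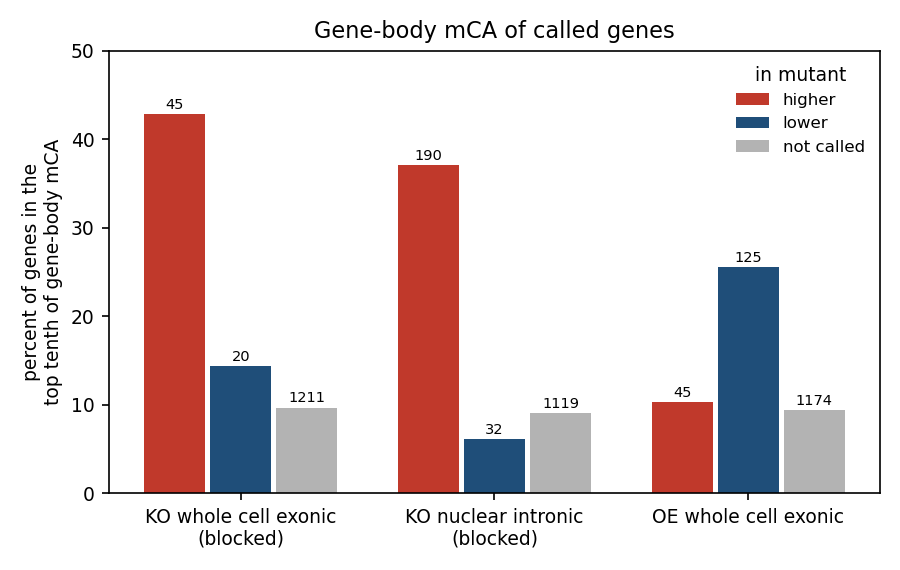
Percent of called genes in the top 10% of gene-body mCA, for genes higher, lower and not called in KO whole cells and KO nuclei (with the replicate block) and in OE (without it). Higher genes stand above lower genes in both KO bars (37.0% against 6.13% in nuclei), and lower genes above higher ones in OE (25.5% against 10.3%).

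The Dnmt3a cKO values come from the authors' deposited table, in which 81 of 15581 genes passed an adjusted p of 0.05 (50 higher, 31 lower in cKO). Dnmt3a itself stood at -0.79 (adjusted p = 4.62e-12) in the authors' deposited table, and Mecp2 at 0.17 (adjusted p = 0.667). In the authors' deposited table the junction scaffold gene Inadl rose by 0.79, the calcium-binding gene Cabp7 by 0.71, Sec14l4 by 0.68, the myosin gene Myo5c by 0.68, Gigyf1 by 0.59, Nrsn2 by 0.58, the serotonin receptor gene Htr1b by 0.57 and the polarity gene Crb2 by 0.55. By the authors' deposited table the troponin gene Tnnc1, which overlaps Nisch on the other strand, fell by 0.89, the Wnt antagonist gene Frzb by 0.65, Tmem90b by 0.61, the hexokinase-like gene Hkdc1 by 0.60, the potassium channel gene Kcnk4 by 0.54, the receptor kinase gene Met by 0.49 and Etnk2 by 0.46. Cabp7, Gigyf1, Htr1b, Crb2 and Tmem90b also overlap a gene on the other strand. In whole-cell exonic counts of the KO cohort Tnnc1 averaged 626 CPM in replicate 1 and 5.47 CPM in the others. How strand was counted in the Dnmt3a cohort was not tested. Among list members in the authors' deposited table Auts2 (0.47), Rps21 (0.43) and Dlk1 (0.28) rose, and Calb1 (-0.37) and Dlg2 (-0.23) fell. All 14 striatal markers and 23 of 24 ribosomal protein genes were positive in the authors' deposited table, without a test of the list. Of the 50 higher and 31 lower genes called in the authors' deposited table, 17 and 4 lay in the top 10% of mCA, and 13 and 9 were over 100 kb. Among all genes of that table the top 10% of mCA held 1431 against 12870 others. Genes over 100 kb numbered 2295 against 13286 others.

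KO and Dnmt3a cKO were compared for shared changes, since DNMT3A writes marks that MeCP2 binds. The whole-cell KO calls shared 4 genes with the authors' deposited table, all in the same direction where 0.192 were expected, and 0 opposite by edgeR against that table (0 also with DESeq2 calls, and 0.200 expected). Auts2 rose in both (0.47 in KO and 0.47 in the authors' deposited table), Necab3, a calcium-binding protein gene, fell in both (-0.44 and -0.37) and Frzb fell in both (-0.75 and -0.65), and the fourth is a clone name. The 2 shared rises and 2 shared falls had Fisher's exact p = 0.00501 and 0.00330. Nuclear KO calls shared 5 genes with the authors' deposited table, among them the cadherin-like gene Fat1 (0.43 and 0.33), Hkdc1 (-0.58 and -0.60) and the cytoskeletal gene Shroom3 (0.56 and 0.41). With the block the whole-cell and nuclear KO calls shared 15 and 22 genes with the authors' deposited table (0.728 and 2.56 expected), and DESeq2 calls shared 15 (0.967 expected). The 4 became 0 without WT replicate 5 or 6 or KO replicate 3, 1 without KO replicate 1 or 6, and 2 without WT replicate 2 or 4 or KO replicate 4 or 5. Across 13722 genes, which are not independent replicates, Pearson's r between the KO fold changes and the authors' deposited table was 0.250 and Spearman's rho 0.310.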

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

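Among the tests in this part, those on replicate 1 were chosen after the result was seen. A sample far from the rest of its group was found in 17 of 166 groups of values (10.2%), where chance gives about 1 in 20.

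Several of these values concern genes that changed in KO. In KO whole cells, log2 CPM of the adhesion gene Sdk1 was lowest in KO replicate 2 (4.79, next 5.10) and that of Bmper highest in KO replicate 5 (4.72). Pappa2 and Glra3 were highest in WT replicate 4 (3.66 and 3.63), and Dnmt3a was highest in KO replicate 6 (7.16). In nuclei Hmgcs2 was lowest in WT replicate 3 (0.70), Ptgfrn highest in WT replicate 6 (5.62), Mndal highest in WT replicate 4 (2.19), Bmper highest in KO replicate 2 (6.92) and Npas4 highest in KO replicate 5 (4.07). Irak1 was lowest in OE replicate 2 (5.02). In whole-cell introns Cerkl was highest in KO replicate 4 (5.37) and Cacna1g in KO replicate 3 (6.30).

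The other values stand in replicate 2, whose whole-cell libraries are the shallowest, while its nuclear libraries are not. The 10 most counted genes held 4.41% of whole-cell intronic counts in KO replicate 2 (next 2.93%) and 4.86% in WT replicate 2 (next 3.18%). The long gene difference was 0.525 in nuclear KO replicate 2 (next 0.0571), and the mCA difference in whole-cell introns was lowest in KO replicate 2, at -0.201. Nuclear replicates 1 and 2 of both genotypes held 11883419 to 14023482 counts, and the other nuclear libraries 7091819 to 8634712. Their 10 most counted genes held 4.32% to 5.54% of counts, against 2.85% to 3.61% in the other nuclear libraries. What sets these replicates apart was not tested.

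H3K27ac ChIP-seq came from other libraries and was set against RNA only under the other observations. By the authors' deposited values 2 genes passed for H3K27ac at the transcription start in KO, Sox5 (0.54) and Cpne6 (-0.51), and 2 genes in OE, Crlf1 (0.98) and Mecp2 (1.39).

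Replicate 1 of both genotypes stood apart in whole-cell exonic counts, with 198 genes in WT and 193 in KO that overlap an opposite-strand gene and lay over 2 log2 units above the other replicates, against at most 1 such gene in any other whole-cell exonic library of the cohort. Counting without strand in these 2 libraries is a candidate explanation, since the SD over overlapping genes was at least 4.43 times that over other genes, and at most 1.94 times in the 44 other sets of counts, in which KO cohort whole-cell libraries appear by exons and by introns. Other cells or another dissection is argued against by intronic counts of the same libraries, where the deviations of WT and KO replicate 1 had a correlation of -0.166. Depth is argued against by the shallower replicate 2, with an SD of 0.401 against 1.31 over the overlapping genes. How these libraries were made stays open, and no further biological explanation was tested.

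Irak1 and intronic Mecp2 stood higher in KO, next to each other on the X chromosome. A copy gain of the whole region is argued against by the 32 other genes within 1 Mb. Their median was -0.0839 in nuclei, with values from -0.593 to 0.120. A variant linked to the region need not move its genes in a common direction, so this median cannot decide on a variant. Of these genes L1cam alone was called and fell by 0.41 (4 genes called with the block, all lower). Plxna3, the lowest of them at 243 kb from Mecp2, was also a called fall in whole-cell introns. The 443 other X genes had a median of -0.00175. TMM scaling brings the median of all genes near 0 (0.00396 in nuclei), so the X gene median cannot decide on depth or scaling. An effect of the knockout allele itself on transcription through the end of Mecp2 and into Irak1 may remain, as a hypothesis. It was not tested, nor was a small linked variant at these genes.

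KO and OE fold changes ran opposite. A shared trend with gene length, expression or mCA is argued against by a correlation of -0.443 across 12643 genes relative to genes alike in all of these (-0.474 before). Chance among the KO cohort's libraries is argued against but not excluded. Only the real split, 1 of 462, was as large (-0.508), while another reached 0.463 in size. Splits that keep numbered pairs and splits of the OE libraries were not compared in this way. Shares of listed cell types cannot be told apart from regulation, since 20 of the 43 shared genes changed by more than the largest of 11 cell type list medians in both (0.416 in KO, 0.537 in OE) and the rest did not. A response to MeCP2 level may account for the opposite signs, as a hypothesis, with strain untested.

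Other splits of the same libraries were compared with the real ones. Chance is argued against for KO whole cells (1 of 100 splits as large, 69 genes, highest other 3, and with pairs kept 1 of 32, 262, highest other 6). The same holds for KO nuclei with pairs kept (1 of 32, 1059, highest other 0 by edgeR). A share of 1 of 32 is the smallest that splits with pairs kept can give. Chance is also argued against for OE (1 of 100, 978, highest other 9) and nuclei against whole cells (1 of 100, 3217, highest other 648). For whole-cell introns the margin was small (1 of 100, 11, highest other 6), with Mecp2 and Irak1 among the 11, so that chance stays open there. In nuclei without pairs 2 of 100 splits were as large, the real one (62) and another with 401, several times as many, which points to a structure of the samples. For the difference of the KO effect between fractions the real count was 0 by edgeR, so that every split is as large (100 of 100, highest other 1) and the splits say nothing about chance.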

How the results depend on the processing

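The block in the overlaps and beside an estimated correlation, the libraries of replicate 1 or 2 left out together, the opposite-strand filter and the overlap with the authors' KO calls were tests chosen after the data were seen. The cause was not tested for any changed result below.

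Mecp2 and Cirbp changed direction with intronic in place of exonic counts in KO whole cells (1.51 and -0.0297). Of 1578 values of named genes there under alternatives 1336 kept their direction and side of the threshold, as did 1301 of 1430 in nuclei, 1140 of 1343 in OE, 1175 of 1200 in whole-cell introns and 190 of 200 between fractions.

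The 69 genes of KO whole cells became 36 with no filter, 345 with DESeq2, 262 with the block, 29 without replicate 1, 84 with the block and without replicate 1 (44 of the 69 among them), 182 with the block and without replicate 2, 110 without genes that overlap an opposite-strand gene, 11 with intronic counts and 22 with both kinds summed. The 62 genes of nuclei became 177 with DESeq2, 1059 with the block, 18 without replicate 1, 786 with the block and without replicate 1, and 555 with the block and without replicate 2. The 11 genes of whole-cell introns became 31 with DESeq2. With 1 library left out, counts ran from 10 to 113, 21 to 73, 579 to 1106 (OE), 7 to 27 (whole-cell introns) and 2371 to 3448 (nuclei against whole cells in WT).

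The 43 genes opposite in KO and OE became 120 and 7 at adjusted p of 0.1 and 0.01, 192 with DESeq2, 142 or 276 with the block (whole cells or nuclei) and 16 without replicate 1, and 7 to 59 with 1 library out. The 4 shared by KO and Dnmt3a cKO became 17 and 0, 15 with DESeq2, 15 or 22 with the block and 16 with the authors' KO calls, and 0 to 4 with 1 library out. With an estimated correlation 0 gene lists passed by camera, and 0 also with the block.

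With means in place of medians the long gene difference was 0.0291 in KO whole cells (exact p = 0.0411) and -0.0674 in OE (exact p = 0.0397). With a boundary of 50 or 200 kb the long gene difference was 0.00789 or 0.0341 in KO whole cells and -0.0248 or -0.0543 in OE. For the top 25% the mCA difference was 0.0104 in KO whole cells (exact p = 0.790) and -0.0310 in OE (exact p = 0.405). The nuclear mCA difference was 0.105 without replicate 1 (exact p = 0.0556) and 0.0702 for the top 25% (exact p = 0.128). With 1 library left out it ran from 0.0763 to 0.126, and the long gene difference from -0.00868 to 0.147 in nuclei, 0.0111 to 0.0276 in KO whole cells, -0.0556 to -0.0244 in OE and -0.0163 to 0.137 in whole-cell introns. The mCA difference ran from 0.0110 to 0.0564 in KO whole cells, -0.0784 to -0.0324 in OE and 0.0336 to 0.116 in whole-cell introns.

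Alternatives planned for counts of the Dnmt3a cohort, OE introns and nuclear exons were not run. The shallowest whole-cell intronic library held 812488 counts, and what depth alone does to the calls was not tested.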

Other observations

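The tests in this part were chosen after the data were seen. Genes in the deposited lists headed MR_meta and MA_meta moved apart in KO and the other way in OE. How the authors made these lists is not stated, so that they cannot be taken as independent of these libraries. In KO whole cells 350 of 412 MR_meta genes were positive, with 15 called, all higher, and a difference from other genes of 0.16 (exact permutation p = 0.00216). Of the MA_meta genes 65 of 515 were positive, with a difference of -0.16 (exact permutation p = 0.00216). In OE 38 of 413 and 447 of 519 were positive, with differences of -0.24 and 0.19 (exact permutation p = 0.00794 each, the smallest that these regroupings can give). In nuclei 348 of 400 MR_meta and 69 of 471 MA_meta genes were positive, with differences of 0.19 and -0.20 (exact permutation p = 0.0649 and 0.00216). Pairing by number is uncertain, above all in KO whole cells. By numbered pairs MR_meta genes were higher in 6 of 6 pairs and MA_meta genes in 0 of 6, in KO whole cells and in nuclei (exact sign-flip p = 0.0313, the smallest that 6 pairs can give, adjusted p = 0.0625). In whole-cell introns 308 of 386 and 110 of 404 were positive, with differences of 0.13 and -0.13 (exact permutation p = 0.182 and 0.00433).

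Crlf1, which rose in OE, was also higher for H3K27ac at its start in the authors' deposited table. Across 14643 genes, which are not independent replicates, H3K27ac at the start and RNA in OE had Spearman's rho = 0.125. In KO it was 0.170 for whole cells and 0.155 for nuclear RNA against H3K27ac at the start, and 0.164 and 0.242 against H3K27ac over gene bodies.

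OE and Dnmt3a cKO shared 23 genes called in opposite directions and 1 in the same direction, where 2.71 and 2.65 were expected. Lphn2 (-0.72 in OE), Auts2 (-0.33), Cabp7 (-0.82), Fat1 (-0.57) and Nell1 (-0.89) fell in OE and rose in the authors' deposited table for Dnmt3a cKO. Met (0.81), Kcnk4 (0.44) and Hkdc1 (0.56) rose in OE and fell in that table.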
